A study of Mus musculus with 6 samples.

How the data were processed

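RNA from 6 C2C12 cultures was measured, 1 Affymetrix array for each of 6 groups: growth medium or differentiation medium, each untreated, with TNF-α at 50 ng/ml or with BTZ at 10 nM. Per the labels, total RNA was extracted with TRIzol, its integrity was read on a Bioanalyzer, and it was amplified and end-labelled with biotin by a whole-transcript protocol. The deposited values are 1 number per probe set and array, taken to be log2 signals because they run from about 2 to 14, as log2 signals of such arrays do. The steps of summarization, background correction and normalization are not given in the sources used here, and no detection calls were used. The 6 columns have close but not identical distributions, and no further scaling was applied for the values reported.

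Of 41345 probe sets, 25335 were in the platform annotation, 23521 named 1 gene symbol and 1814 named several. The 16010 with no gene named were not used for genes. For 23328 of the single-symbol probe sets the Entrez number was in the RefSeq table, and the symbol differed in 0 of them. A gene's value was the mean of its single-symbol probe sets, which gave 22180 genes, 1082 of them with more than 1 probe set. Of the 814 such genes above the floor, 192 had probe sets that differed by 1 log2 unit or more in at least 1 comparison. The floor was the median of all values, 5.06, and a gene was used where its highest array reached it, which left 13652 genes.

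For each of 5 comparisons (untreated differentiation against growth medium, and TNF-α and BTZ against the untreated array of the same medium) the log2 difference of 2 arrays was taken, and genes at least 2-fold higher or lower were counted. Where the lower array of a gene is under the floor its fold is compressed by background; this holds for 222, 46, 168, 99 and 312 of the genes past 2-fold, with the comparisons in the order medium, TNF-α and BTZ in growth medium, TNF-α and BTZ in differentiation medium. The share past 2-fold of genes under the floor is set by the floor itself, which looks at the highest array, and is not used as a measure of noise. Among unnamed probe sets above the floor the share past 2-fold was 10.7%, 6.85%, 17.0%, 8.59% and 18.2% in the same order. Unchanged arrays were simulated in 100 sets, with the residual spread of the additive fit (median SD 0.185) after its moderation by eBayes. They gave between 134.69 and 137.08 genes past 2-fold. That spread also holds any difference of a treatment effect between media, so these numbers are not array noise alone. Effects were compared between media as differences of differences over 4 arrays, without a test. Overlaps were set beside the number expected for independent lists. Correlations across genes between comparisons that share a control were set beside simulated ones.

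An additive model of medium and treatment was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend), with Benjamini-Hochberg adjustment at 0.05 over the genes above the floor. It leaves 2 residual degrees of freedom. Simulated spikes were used to check it: 100 of 100 genes with a medium effect of 3 log2 units and 100 of 100 with 1.5 were recovered, with 8 false calls, and 100 of 100 for TNF-α with 16 false calls. For TNF-α in growth medium with 2 arrays, 93 of 100 genes at 1.5 log2 units and 100 of 100 at 3 were past 2-fold, with 7 false calls. These simulations used the spread that eBayes expects at each gene's level, and the same treatment effect in both media. They hold no difference of a treatment effect between media, which enlarges the residual of the real fit. Real effects of these sizes can therefore be missed: for TNF-α, 6 of 36 NF-kB targets passed, with a mean effect of 1.49.

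The 26 gene lists were fixed beforehand: sarcomere, excitation-contraction coupling, myogenic regulators and fusion, inhibitors of differentiation, mitotic cell cycle, DNA replication, cell cycle inhibitors, NF-kB targets, chemokines and cytokines, interferon-stimulated genes, MHC class I and immunoproteasome, constitutive proteasome, ubiquitin ligases and autophagy of muscle wasting, heat shock, unfolded protein and integrated stress response, NRF2, p53 and apoptosis, extracellular matrix, glycolysis, mitochondrial respiration, ribosomal proteins, cholesterol synthesis, 3 lists of other cell types, and housekeeping. Each list's median was ranked among 10000 random lists of the same size, matched on mean level in 20 bins; inside the random range means between the 2.5th and 97.5th percentiles. Lists were also tested with limma's camera, with a preset correlation of 0.01 and with an estimated one. Members with no single-symbol probe set, such as Nfkb1 and Runx2, were not measured. Genes named in the text were the 8 highest and 8 lowest of each comparison, leaving out predicted genes, small RNAs and receptor families; the 4 members with the largest difference in lists primary to a comparison; 2 members of other lists outside the random range; the 5 with the smallest adjusted p per direction of the additive fit; the 5 largest per direction for differences between media; and a few genes fixed beforehand (among them Myod1, Myog, Fbxo32, Trim63 and Psmb5).

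Alternatives tried were quantile normalization, arrays shifted to the same median, no floor, a floor at the 75th percentile of all values, thresholds of 1.5-fold and 3-fold, the probe set with the highest level per gene, means in place of list medians, all measured list members, other forms of eBayes, no covariate, and leaving out each array in turn. A pseudocount was not used, since the values were already on the log2 scale. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.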

Results

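C2C12 is a mouse myoblast line that divides in serum-rich medium and fuses into multinucleated muscle fibres (myotubes) when serum is lowered. Total RNA from 6 C2C12 cultures was measured on 1 Affymetrix whole-transcript array each. The cultures crossed 2 media with 3 treatments, so there were 6 groups of 1 array. In growth medium, which held 10% fetal bovine serum, the groups were untreated, TNF-α at 50 ng/ml for 24 h and BTZ at 10 nM for 24 h. In 2% differentiation medium the groups were untreated, TNF-α at 50 ng/ml and BTZ at 10 nM, with treatment on day 4 and harvest on day 5. TNF-α is an inflammatory cytokine that activates the transcription factor NF-kB. The labels do not spell out BTZ, which usually stands for bortezomib, an inhibitor of the proteasome. The median log2 value over 41345 probe sets was between 5.01 and 5.11 on the 6 arrays, and 13652 genes reached the floor of 5.06 on at least 1 array. No group had a replicate, so differences between 2 arrays carry no error and no p-value, and the number of arrays limits their precision.

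The comparison of the 2 untreated cultures asked how cells in differentiation medium differed from cells in growth medium. Muscle genes were far higher in differentiation medium. Of 41 genes of the sarcomere (the contractile unit of muscle), 37 were at least 2-fold higher and 0 lower, with a median log2 difference of 3.63. Myh3, the embryonic myosin heavy chain, differed by 6.67, the giant scaffold protein titin (Ttn) by 6.21, the fast light chain Mylpf by 6.12 and nebulin (Neb) by 6.11. Among 27 genes of excitation-contraction coupling and the muscle membrane, 22 were at least 2-fold higher (median 2.23), including the acetylcholine receptor subunit Chrng at 5.73 and the calcium store protein Casq2 at 5.71. Of 15 myogenic regulators and fusion genes 10 were higher (median 1.61), among them the fusion protein myomaker (Mymk) at 6.10, myogenin (Myog) at 4.19, the integrin Itga7 at 2.53 and Igfn1 at 1.78.

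Genes of dividing cells were lower in differentiation medium. All 36 mitotic genes above the floor were at least 2-fold lower, with a median of -2.92, including the spindle checkpoint kinase Bub1 at -3.89, the kinetochore gene Nuf2 at -3.60, the spindle motor Kif11 at -3.54 and survivin (Birc5) at -3.51. Of 39 DNA replication genes 31 were lower and 1 higher (median -1.66), with the helicase subunit Mcm5 at -2.86 and the replication-coupled methylation factor Uhrf1 at -2.67. Of 10 cell cycle inhibitors 1 was higher and 1 lower, with a median of -0.11 and a mean of 0.08. Cdkn1a, an inhibitor that is also a p53 target, was higher by 3.32, and the p53 target Eda2r by 3.34. The p53 list had a median of 0.46, with 6 of 31 genes higher and 1 lower. In the extracellular matrix list 7 of 35 genes were higher and 2 lower (median 0.56, and 0.36 over all measured members), with the proteoglycan decorin (Dcn) at 4.25 and periostin (Postn) at 2.58. Of 36 ubiquitin ligase and autophagy genes tied to muscle wasting, 4 were higher (median 0.32), among them the ligases Trim63 at 1.82 and Fbxo32 at 1.43. Of 25 NRF2 antioxidant genes 8 were lower and 0 higher (median -0.48), including Nqo1 at -3.55 and Gsta4 at -2.22. The 33 ribosomal protein genes had a median of -0.42, with Rpl37 at -1.33 and Rps13 at -1.06, and the 41 stress response genes of the unfolded protein and integrated response one of -0.22, with Aldh1l2 and Psat1 both at -1.36.

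In total 660 genes were at least 2-fold higher in differentiation medium and 535 at least 2-fold lower. That is 8.75% of the genes above the floor, and 10.7% of the 8413 probe sets above it with no gene named were past 2-fold. Simulated unchanged arrays gave 134.69 genes. The 20 glycolysis genes had a median of -0.04, a mean of 0.38 and, after quantile normalization, a median of 0.09, which lies inside the range of random lists.

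**Figure D1:**
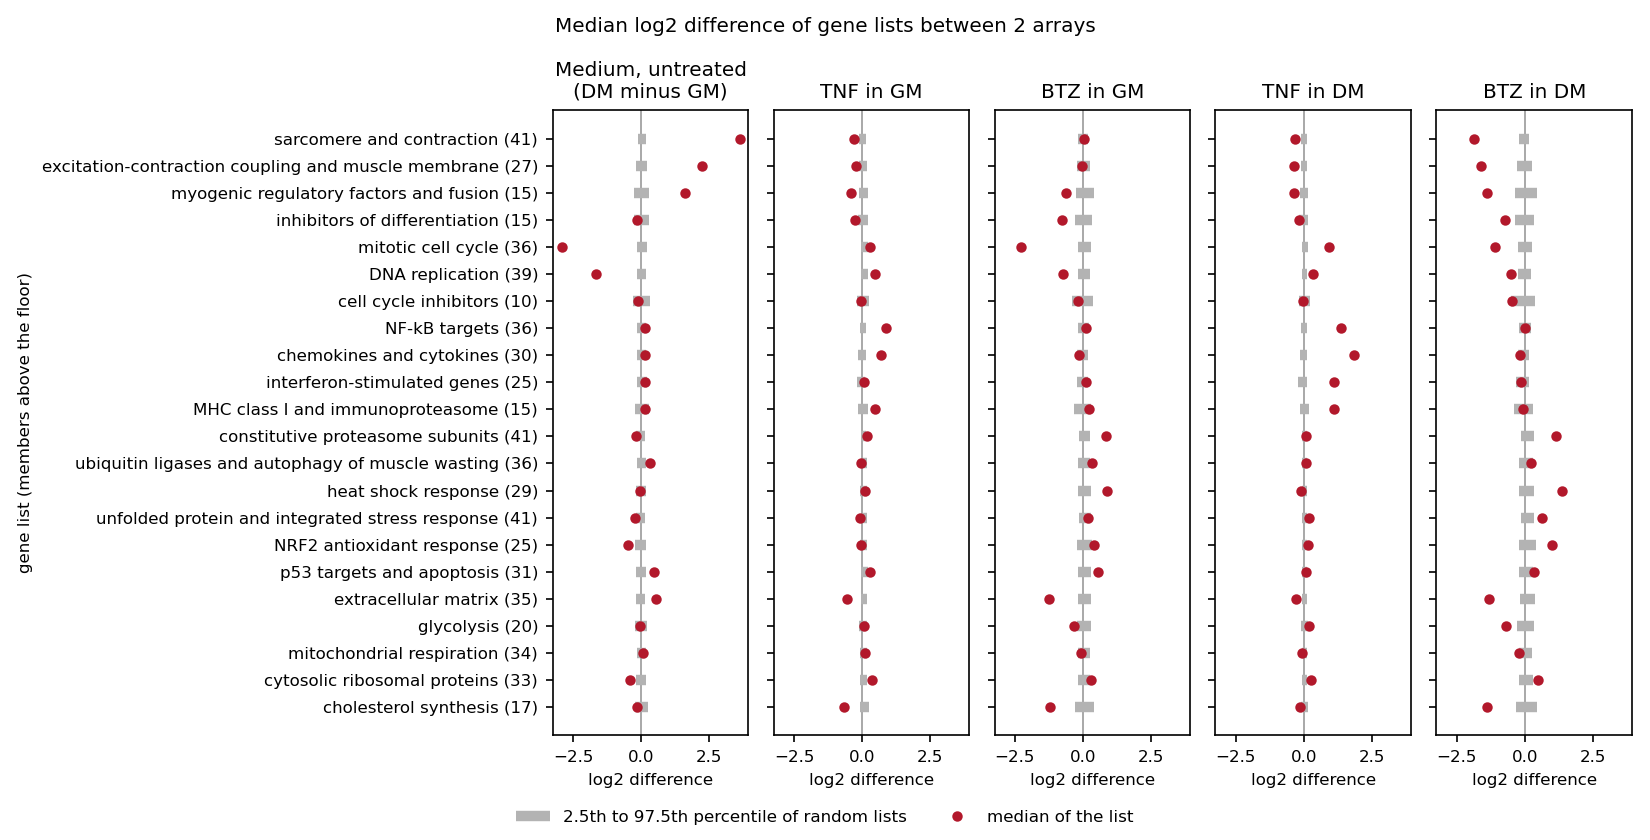
Median log2 difference of 22 gene lists in each of the 5 comparisons of 2 arrays (points), with grey bars over the random range of medians of lists of the same size and level. The sarcomere median is 3.63 for differentiation against growth medium and -1.86 for BTZ in differentiation medium, and the proteasome median is 0.85 and 1.14 with BTZ.

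TNF-α in growth medium was compared with the untreated culture of that medium. Inflammatory genes were higher: the acute-phase gene Saa3 by 6.31 on the log2 scale, the chemokines Ccl2 by 5.11, Ccl5 by 4.82 and Ccl7 by 3.47, and Serpinb2, an inhibitor of plasminogen activators, by 4.30. Of 36 NF-kB targets 17 were at least 2-fold higher and 0 lower (median 0.89), among them the inhibitor Nfkbie at 2.94, the death receptor Fas at 2.80 and the collagenase Mmp13 at 2.63. Of 30 chemokines and cytokines 12 were higher and 2 lower (median 0.69, and 0.29 over all measured members with those under the floor), with Cxcl1 at 2.86. Of 15 genes of antigen presentation on MHC class I and of the immunoproteasome 3 were higher (median 0.50), with the peptidase Erap1 at 1.78, H2-K1 at 1.49 and Psmb10 at 1.41. Of 25 interferon-stimulated genes 2 were higher, and the median of 0.07 was inside the random range and became -0.01 with the arrays shifted to the same median.

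Several genes of matrix and metabolism were lower with TNF-α in growth medium. The carbonic anhydrase Car3 differed by -4.89, its relative Car2 by -2.61, the potassium channel Kcnj2 by -3.51, the small proteoglycans Ogn, Omd and Aspn by -3.35, -3.09 and -2.86, and Igfbp5, which binds insulin-like growth factors, by -2.33. Of the matrix list 8 of 35 genes were lower and 0 higher (median -0.54, and -0.30 over all measured members), including Col6a1 at -1.52 and Col6a2 at -1.47. Of 17 cholesterol synthesis genes 4 were lower (median -0.65), with Insig1 at -1.17 and Hmgcs1 at -1.14. The myogenic list had 1 gene higher and 1 lower (median -0.41, and -0.30 over all measured members, Eya4 at -1.26 and Pax7 at -0.76), and the sarcomere list 1 higher and 0 lower (median -0.30, Tnnt2 at 1.20 and Acta1 at -0.85). Among inhibitors of myogenic differentiation the median was -0.25, with Id3 at -1.28 and Hey1 at -0.84. Mitotic and replication genes lay slightly higher, with medians of 0.32 and 0.47 and 0 members past 2-fold; Melk differed by 0.80 and Gins1 by 0.91. The wasting ligase Fbxo32 was higher by 1.48, while the wasting list had a median of -0.04 and a mean of 0.028. The 41 proteasome genes had a median of 0.18 with Psmd10 at 1.06, and the p53 targets one of 0.31 with Plk2 at 1.55. Ribosomal protein genes had a median of 0.37, with Rps7 at 0.96.

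In this comparison 134 genes were at least 2-fold higher and 139 lower, which is 2.00% of genes above the floor. In 100 simulated sets of unchanged arrays with the spread left by the additive fit, 137.08 genes passed on average, a figure that also holds any difference of a treatment between media. The share higher among genes past 2-fold was 49.1%, against 35.9% with the arrays shifted to the same median and 43.3% after quantile normalization.

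TNF-α in differentiation medium, given to cultures 4 days into differentiation, went with larger differences in immune genes. Saa3 was higher by 8.79, Ccl5 by 8.30, the lectin receptor Clec4e by 7.61, complement factor B (Cfb) by 6.97, Ccl2 by 6.61, the NADPH oxidase subunit Cybb by 5.81, the pentraxin Ptx3 by 5.76 and the chemokine Cxcl9 by 5.52. Of the NF-kB targets 24 of 36 were at least 2-fold higher and 0 lower (median 1.38), with inducible nitric oxide synthase (Nos2) at 4.58 and Nfkbia at 3.18. Of the chemokines and cytokines 19 of 30 were higher and 2 lower (median 1.84, and 1.27 over all measured members). Interferon-stimulated genes were higher as a group, 14 of 25 (median 1.13, and 0.55 over all measured members), with the guanylate-binding proteins Gbp7 at 2.96 and Gbp5 at 2.85. Of 15 MHC class I and immunoproteasome genes 10 were higher (median 1.13), with Psmb10 at 2.79 and H2-K1 at 2.02.

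Muscle genes were slightly lower with TNF-α in differentiation medium. Of 41 sarcomere genes 2 were at least 2-fold lower (median -0.31), the slow myosin-binding protein Mybpc1 at -1.52 and the fast myosin Myh4 at -1.08. The excitation-contraction median was -0.35 with 0 of 27 past 2-fold, and the myogenic median -0.36, with Igfn1 at -1.18 and the adhesion protein Cdh15 at -1.15. The wasting ligases Trim63 and Fbxo32 differed by 0.35 and -0.18; their list had a median of 0.07 (-0.01 with shifted arrays), with the mitophagy receptor Bnip3 at 1.40. Of 36 mitotic genes 15 were higher and 0 lower (median 0.93), with Bub1 at 1.68, and replication genes had a median of 0.34, with Tk1 at 1.12. Lower genes included Aspn at -4.18, Omd at -3.58, the matrix protein Cilp at -3.34 and Car3 at -3.31, and the matrix list had a median of -0.29 (-0.175 over all measured members) with 4 of 35 lower and 1 higher. The proteasome list had a median of 0.07, which became -0.01 with shifted arrays. In all, 274 genes were at least 2-fold higher and 120 lower, or 2.89% of genes above the floor, against 136.11 genes in simulated unchanged arrays.

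The TNF-α effect was set against itself between media, as a difference of differences over 4 arrays with no test. Interferon-stimulated genes had a median difference of 0.72 towards differentiation medium, chemokines 0.87, MHC class I genes 0.57, mitotic genes 0.57 and NF-kB targets 0.36, while sarcomere genes had -0.11. Cybb (5.64), Cfb (5.57), Cxcl9 (5.41), the lipopolysaccharide-binding protein Lbp (4.87) and Ptx3 (4.36) leaned most towards differentiation medium. Cybb, Cxcl9 and Lbp were under the floor in the other 3 arrays compared, so their exact differences and order rest on background. At the other end were Serpinb2 (-3.45), which was higher mainly in growth medium, and Cilp (-2.76), which lay under the floor in growth medium and was lower with TNF-α in differentiation medium. At least 2-fold higher in both media were 74 genes, against 2.69 for independent lists, and 39 were lower in both, against 1.22. The correlation of the 2 effects across genes, which are not independent replicates, was 0.476, and these comparisons share no array.

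BTZ in growth medium was compared with the same untreated culture. Genes for protein quality control were higher. Of 41 proteasome subunit genes 9 were at least 2-fold higher and 0 lower (median 0.85), with the ubiquitin receptor subunit Psmd4 at 1.63, the activator Psme4 at 1.26, Psmb6 at 1.19 and Psmc4 at 1.18. Of 29 heat shock genes 12 were higher and 1 lower (median 0.88), with the chaperones Cryab at 3.14, Hspa1b at 2.93, Dnaja4 at 1.99 and Hsph1 at 1.80. In the unfolded protein and integrated stress list 11 of 41 were higher and 0 lower, led by the cystine transporter Slc7a11 at 2.60 (3.64 with its highest probe set), the phosphatase subunit Ppp1r15a at 2.60, Sesn2 at 2.32 and the transcription factor Atf3 at 2.06; the median of 0.19 was inside the random range and the mean was 0.49. The NRF2 list had 5 of 25 higher (median 0.41, Srxn1 at 1.57), the p53 list 11 of 31 (median 0.54, Eda2r at 2.71 and Plk3 at 2.65), and the wasting list 7 of 36 (median 0.36), among them the autophagy genes Gabarapl1 at 1.53, Atg12 at 1.52 and Sqstm1 at 1.17.

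Genes of dividing cells and of matrix were lower with BTZ in growth medium. All 36 mitotic genes were at least 2-fold lower (median -2.29), including Nuf2 at -3.30 and Birc5 at -3.15, and 13 of 39 replication genes were (median -0.71), including Tk1 at -2.64. Of 35 matrix genes 20 were lower and 2 higher (median -1.23, and -1.03 over all measured members), with the collagens Col1a2 at -4.06 and Col3a1 at -3.58. Car3 differed by -4.995, the growth factor Hgf by -4.47 and Ogn by -4.20. Of 17 cholesterol genes 11 were lower (median -1.22), with Hmgcs1 at -2.61 and Fdft1 at -1.82. Of 15 inhibitors of differentiation 6 were lower (median -0.77), with Id3 at -2.20 and Hes1 at -1.93, and of 15 myogenic genes 3 were (median -0.63, and -0.26 over all measured members), with Myf5 at -1.84 and Cdh15 at -1.38. The sarcomere list, near the floor in this medium, stood at 0.05, inside the random range, with 3 genes higher and 3 lower. The glycolysis median was -0.31, with Eno3 at -2.46 and Ldha at -1.44. The ribosomal median was 0.30, with Rpl30 at 0.82. NF-kB targets had a median of 0.10, also inside the random range. In all 681 genes were at least 2-fold higher and 841 lower, or 11.1% of those above the floor, against 135.22 genes in simulated unchanged arrays. Unnamed probe sets had the opposite balance, 1073 higher and 360 lower. The share higher among genes past 2-fold was 44.7%, against 49.1% with shifted arrays and 36.1% after quantile normalization.

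**Figure D2:**
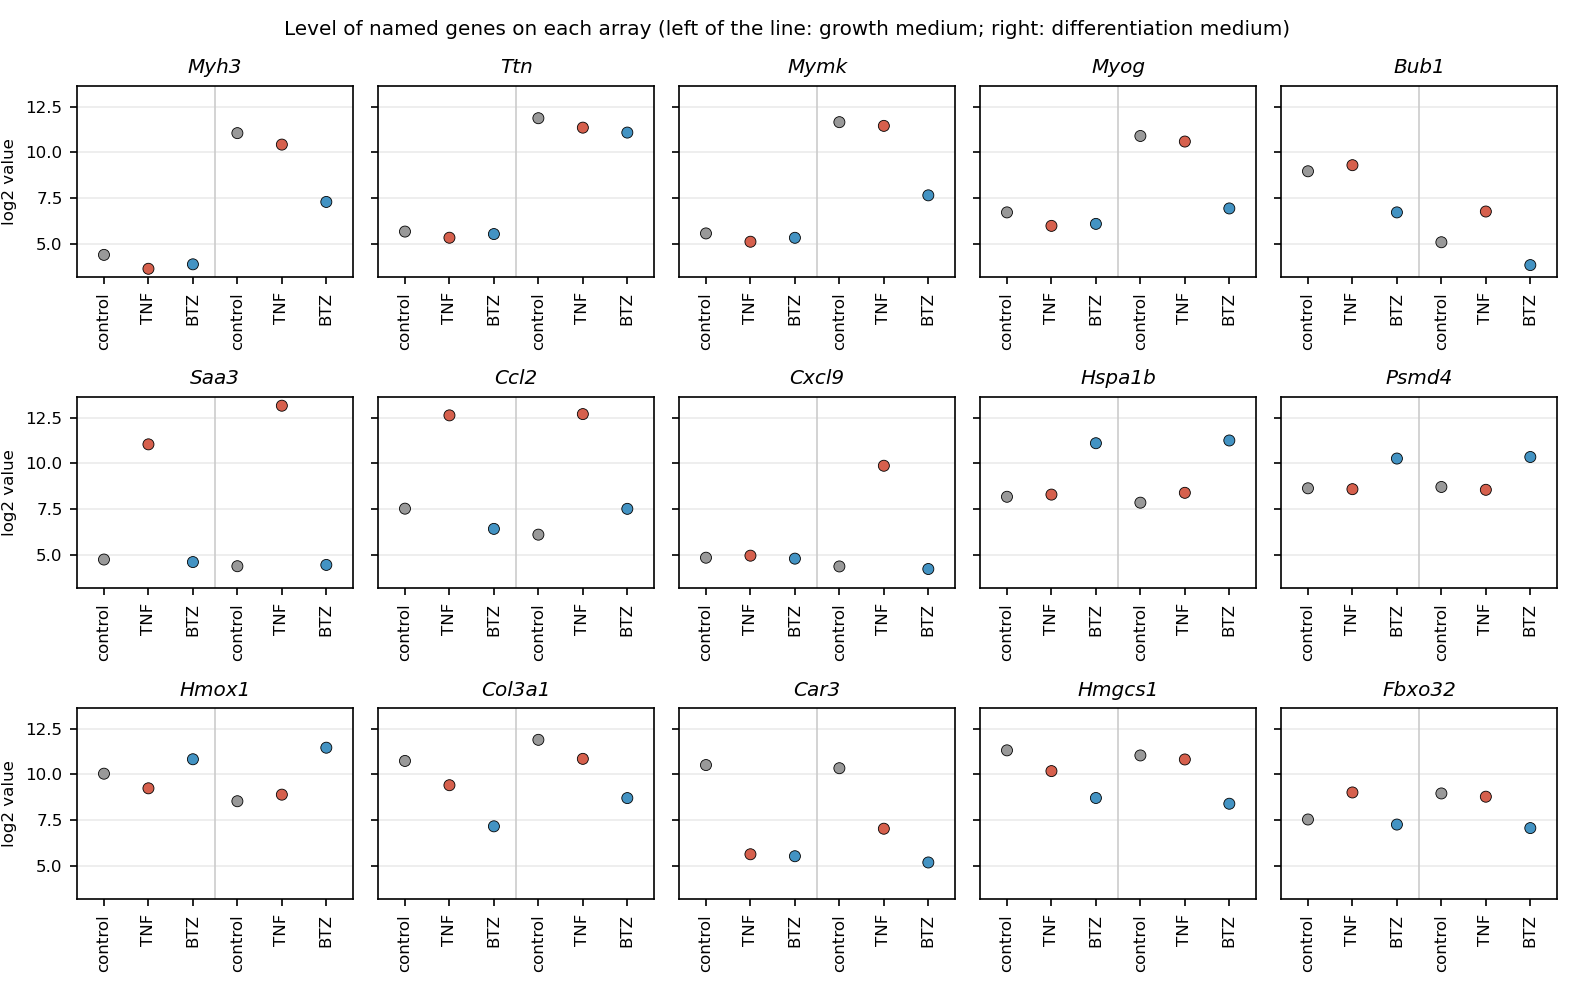
Log2 level of 15 genes on each of the 6 arrays, with growth medium left and differentiation medium right of the line in each panel and untreated in grey, TNF-α in red and BTZ in blue; each point is 1 array. Myog is higher in untreated differentiation medium by 4.19 and lower there with BTZ by a log2 difference of -3.97, and Saa3 is higher with TNF-α by 6.31 and 8.79.

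BTZ in differentiation medium went with lower muscle genes and higher stress genes. Of 41 sarcomere genes 32 were at least 2-fold lower and 1 higher (median -1.86), with cardiac actin (Actc1) at -4.48, Myom1 at -3.98, Tnni2 at -3.93 and Myh4 at -3.86. Of 27 excitation-contraction genes 21 were lower and 0 higher (median -1.62), with Chrng at -5.27 and the calcium pump Atp2a1 at -4.59. Of 15 myogenic genes 10 were lower (median -1.39, and -1.16 over all measured members), including Mymk at -4.01, Myog at -3.97 and Myod1 at -2.90. Inhibitors of differentiation were lower too, 6 of 15 (median -0.72), with Id3 at -2.98 and Hes1 at -1.66. The wasting ligases Fbxo32 and Trim63 were lower, at -1.90 and -1.11, while the autophagy genes Gabarapl1 and Sqstm1 of the same list were higher, at 1.74 and 1.67; that list had 5 higher, 4 lower and a median of 0.22 inside the random range.

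The protein quality lists were higher in this medium also. Of 41 proteasome genes 25 were at least 2-fold higher and 0 lower (median 1.14), with Psma1 at 1.83, Psmd14 at 1.81 and Psmb2 at 1.71, while Psmb5, a catalytic subunit, was higher by 0.83. Of 29 heat shock genes 18 were higher and 1 lower (median 1.37), with Hspa1b at 3.41, Dnajb1 at 2.78 and Hsph1 at 2.77. Of 41 unfolded protein and integrated stress genes 14 were higher and 1 lower (median 0.64), with Atf3 at 3.50, Slc7a11 at 3.05 (5.04 with its highest probe set) and Aldh1l2 at 3.02. Of 25 NRF2 genes 12 were higher and 1 lower (median 0.9999), with haem oxygenase (Hmox1) at 2.93, Gclm at 2.68 and Srxn1 at 2.67. The p53 median was 0.36, with Plk3 at 2.81. Of 36 mitotic genes 22 were lower (median -1.10), including Anln at -3.14 and Ccna2 at -2.57, and of 39 replication genes 6 were (median -0.50), with E2f2 at -2.00. Of 35 matrix genes 21 were lower and 1 higher (median -1.30, and -1.16 over all measured members), with Dcn at -4.40 and Thbs1 at -3.24; of 17 cholesterol genes 14 were lower (median -1.40), with Fdft1 at -3.19; of 20 glycolysis genes 9 were (median -0.70), with Eno3 at -3.45. The ribosomal median was 0.48, with Rps15 at 1.37. In all 826 genes were at least 2-fold higher and 1216 lower, or 15.0% of those above the floor, against 135.48 genes in simulated unchanged arrays. Unnamed probe sets again had the opposite balance, 1201 higher and 334 lower. Shifting the arrays to the same median moved the median of all genes here from 0.0030 to 0.108, and the share higher among genes past 2-fold went from 40.5% to 50.0%, while quantile normalization took it to 33.8%.

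The BTZ effect was set against itself between media in the same way, with no test. The sarcomere median of this difference was -1.94 and the excitation-contraction median -1.25, while mitotic genes had 1.16, NRF2 genes 0.76, heat shock genes 0.46 and cholesterol genes -0.42. Chrng (-5.60), Atp2a1 (-4.97), Myom1 (-4.61), the neuregulin receptor Erbb3 (-4.60) and Actc1 (-4.38) stood at the low end, and cyclin D1 (Ccnd1, 3.38), the cysteine synthesis enzyme Cth (3.19), Nqo1 (2.93), Kif15 (2.84) and Csf1 (2.71) at the high end. The sarcomere list had a median level of 5.27 in untreated growth medium, near the floor, and Atp2a1, Myom1, Erbb3 and Actc1 lay under it, so for these 4 genes, and other members at background, lower levels with BTZ could not be seen there. Members well above it could be lower, as Actn3 was at -1.25 and Des at -1.13. In untreated differentiation medium Kif15 and Cth lay under the floor, and the mitotic list, with a median level of 6.34 there and 5.20 with BTZ, had members under it, which limits how far their values could go down. The 2 media also shared a large part of the BTZ effect, with 370 genes higher in both against 41.2 for independent lists, 478 lower in both against 74.9, and a correlation across genes of 0.662.

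With BTZ on both sides, differentiation and growth medium differed less than without treatment. Between the 2 BTZ arrays 210 genes were at least 2-fold higher and 291 lower in differentiation medium, against 660 and 535 untreated and 799 and 662 with TNF-α. The sarcomere median of this difference was 3.63 untreated, 2.91 with TNF-α and 0.86 with BTZ, the myogenic median was 1.61, 1.12 and 0.43, and the mitotic median was -2.92, -2.36 and -1.76. Of the 799 genes at least 2-fold higher in differentiation medium between the TNF-α arrays, a set chosen without the untreated arrays, 442 (55.3%) were at least 2-fold lower with BTZ in differentiation medium and 21 higher, against 8.91% and 6.05% of all genes. Of the 662 genes lower in differentiation medium, 92 (13.9%) were lower still with BTZ and 74 (11.2%) higher, with a median of -0.09.

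**Figure D3:**
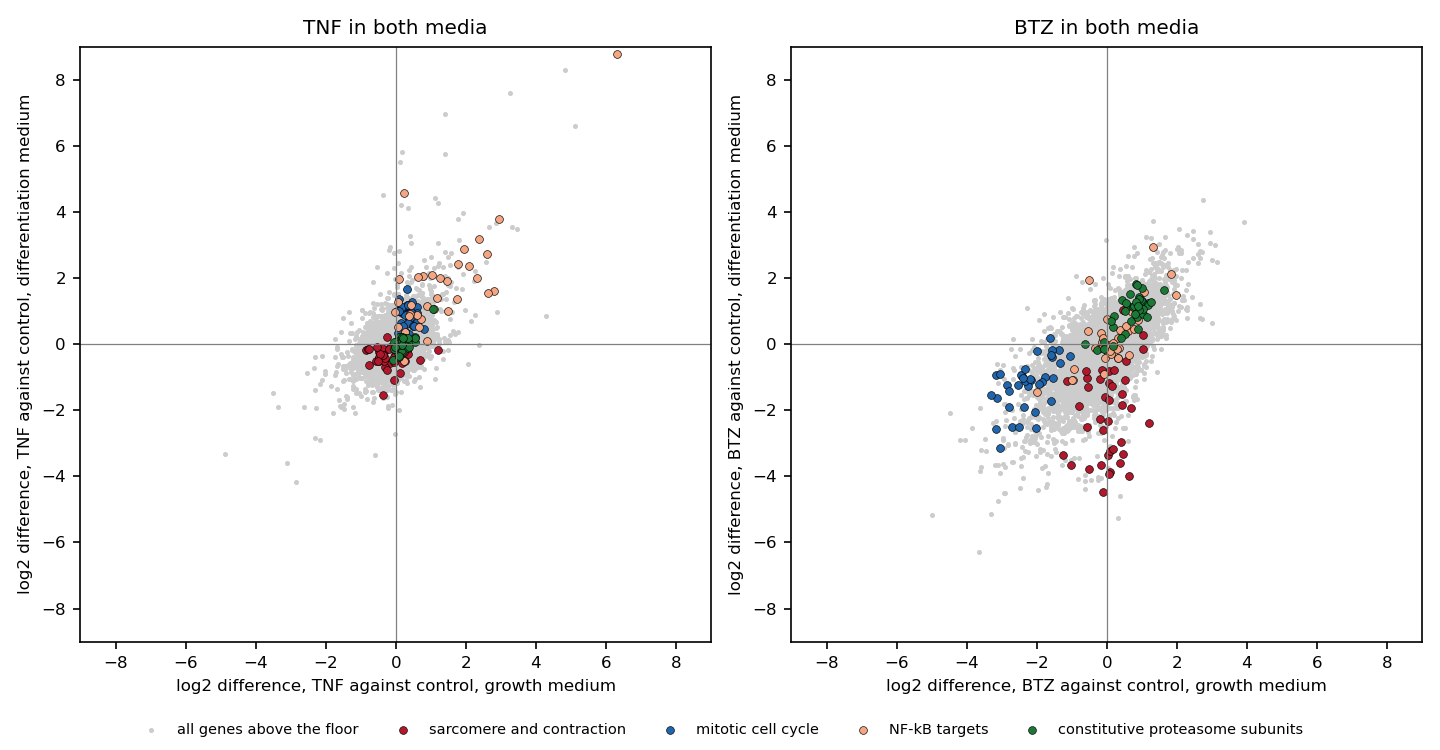
Log2 effect of TNF-α (left) and BTZ (right) on each gene above the floor in growth medium (x axis) and differentiation medium (y axis); grey points are all genes, red sarcomere, blue mitotic, orange NF-kB targets and green proteasome genes. With BTZ the sarcomere genes, whose median level of 5.27 in untreated growth medium is near the floor, have a median of 0.05 on the x axis and -1.86 on the y axis, while the proteasome genes lie above 0 on both, with medians of 0.85 and 1.14.

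TNF-α and BTZ were set side by side within and across media. Both went with lower levels of Car3, Omd, Aspn and Ogn in all 4 treated cultures. In growth medium 101 genes were at least 2-fold lower with both, against 8.56 for independent lists, and 18 higher with both, against 6.68. In differentiation medium 85 were lower with both (10.7 if independent) and 33 higher (16.6). These comparisons share a control array, so the pairs without a shared array were counted too: 89 genes were lower with TNF-α in growth medium and BTZ in differentiation medium (12.4 if independent), and 50 lower with TNF-α in differentiation medium and BTZ in growth medium (7.39). The correlation of the 2 treatments across genes was 0.275 in growth medium and 0.254 in differentiation medium. Simulated unchanged arrays with a shared control gave 0.499 in each. The shared control sets that value by construction and real effects add spread, so the lower values decide nothing. The covariance was 0.0730 and 0.0897, above the simulated 0.0550. The simulated spread also holds any difference of a treatment effect between media. For the pairs without a shared array the correlation was 0.283 and 0.0387.

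An additive limma fit of medium and treatment over the 6 arrays was the one test that the layout allowed. Its 2 residual degrees of freedom also hold any difference of a treatment effect between media. In this fit muscle genes rose and cell cycle genes fell in differentiation medium: Ttn rose by 5.93 (SE 0.17, adjusted p 9.51e-04) and Acta1 by 5.34 (SE 0.23, adjusted p 0.0045), while Mcm3 changed by -2.53, Kif23 by -2.80 and Hells by -2.84 (adjusted p 0.0051 each), in the same direction in all 3 treatments. With TNF-α, Saa3 rose by 7.55, Ccl7 by 3.48, Cxcl1 by 3.27, the NF-kB inhibitor Tnfaip3 by 2.67 and Vegfc by 2.24, while Omd fell by 3.34 and Spon2 by 2.57 (adjusted p 0.0399 each, in 2 of 2 media). With BTZ, Hspa1b rose by 3.17, Plk3 by 2.73 and Ppp1r15a by 2.67, while Col3a1 fell by 3.39, Omd by 3.72 and Col1a1 by 2.90 (adjusted p 0.0065 each), and Thbs1 fell by 3.34 (adjusted p 0.0053), in 2 of 2 media.

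By list, counts are given over all genes at a Benjamini-Hochberg adjusted p of 0.05 and then adjusted over the list alone. For the medium, 16 and 37 of 41 sarcomere genes rose, 34 and 36 of 36 mitotic genes fell and 29 and 38 of 39 replication genes fell. For TNF-α, 6 and 24 of 36 NF-kB targets, 3 and 15 of 30 chemokines and 0 and 8 of 15 MHC class I genes rose, against 0 and 1 of 25 interferon-stimulated genes. For BTZ, 28 and 31 of 41 proteasome genes rose, 19 and 22 of 29 heat shock genes rose, 28 and 33 of 36 mitotic genes fell, 20 and 27 of 35 matrix genes fell and 11 and 14 of 17 cholesterol genes fell, against 4 and 1 of 41 sarcomere genes, 2 and 2 of 27 excitation-contraction genes and 2 and 3 of 15 myogenic genes. Over all genes 213 rose and 337 fell with the medium, 11 and 2 with TNF-α, and 998 and 935 with BTZ; at an unadjusted p under 0.05 the numbers were 3092, 896 and 4340. These counts changed strongly when single arrays were left out. For the medium, leaving out either array of a treatment gave nearly the same counts, since its partner alone no longer bears on the medium effect. Without the untreated growth medium array limma gave 1 and 0 genes for the medium (1470 unadjusted), 0 and 0 for TNF-α (597) and 0 and 0 for BTZ (2362). Without the untreated differentiation medium array it gave 1 and 0 (1478), 0 and 0 (368) and 0 and 0 (2209). Without the TNF-α arrays of growth and differentiation medium in turn the medium counts were 28 and 83, then 28 and 87; those of TNF-α were 20 and 2, then 1 and 1; those of BTZ were 575 and 683, then 606 and 707. Without the BTZ arrays in turn they were 1685 and 1575, then 1680 and 1578 for the medium; 138 and 86, then 133 and 78 for TNF-α; 1881 and 1983, then 1343 and 1292 for BTZ. The set test camera with a preset correlation of 0.01 called 16, 19 and 17 of the 26 lists for medium, TNF-α and BTZ. With an estimated correlation it called 0, with smallest adjusted p of 0.467, 0.422 and 0.484. That form rests on the 2 residual degrees of freedom, so it could hardly call a list, and its 0 decides nothing. Even the mitotic list, with a mean medium effect of -2.35, had an unadjusted camera p of 0.0827 in that form. The estimated correlation was 0.709 for sarcomere, 0.602 for proteasome and 0.558 for mitotic genes, but 0.0177 for the p53 list and -0.0447 for inhibitors of differentiation. Where members vary together far more than the preset 0.01, the preset form gives p-values that are too small. Its calls for such lists therefore overstate the evidence.

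Marker lists for other cells and for RNA quality served as controls. The 13 housekeeping genes had medians of -0.22 for the medium, 0.18 and -0.08 for TNF-α and BTZ in growth medium, and 0.14 and -0.02 in differentiation medium (0.08 for the last with shifted arrays), all inside the random range. Of 4 osteoblast and chondrocyte markers above the floor the medians lay between -0.35 and 0.12, inside that range. The 9 adipocyte markers had -0.23, -0.40, -0.27, -0.18 and -0.28 in the same order, of which -0.40 for TNF-α in growth medium lay outside the random range. Over all measured adipocyte markers it was -0.158, and the values for the medium and for BTZ in growth medium were -0.0682 and -0.0708. With TNF-α in growth medium Plin4 stood at -2.01 and Lpl at -0.98. The 4 leukocyte and endothelial markers had a median of 0.96 with BTZ in growth medium, outside the random range (0.0705 over all measured members), where Cd14 was higher by 2.01 and Cd68 by 1.17, and 0.36 in differentiation medium. The 34 mitochondrial respiration genes had medians of 0.08, 0.10, -0.08, -0.07 and -0.20.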

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

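The results in this part were picked out by 2 fixed rules. In the first, the effect of a treatment went in opposite directions in the 2 media. In the second, probe sets that the comparisons leave out passed 2-fold in both media more often than independent lists would. With 1 array per group none of the differences between media was tested.

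Some values pointed opposite ways in the 2 media. Genes of the unfolded protein and integrated stress response had a median log2 difference of -0.078 with TNF-α in growth medium and 0.21 in differentiation medium, both outside the range of random lists. In growth medium the mean over members was 0.033, with 1 of 41 genes past 2-fold, so the direction there depends on the summary. The chemokine gene Ccl2 was lower with BTZ in growth medium, at -1.11, and higher in differentiation medium, at 1.41. Cyclin D1 (Ccnd1), which drives entry into the cell cycle, stood at -2.27 with BTZ in growth medium and 1.10 in differentiation medium. Slow troponin C (Tnnc1) stood at 1.21 and -2.38 in the same order. Among single genes the rule covered only those picked to be named, so Tmem38a (1.15 and -2.40) and Adam4 (1.07 and -1.06) with BTZ were passed over. Such genes were few. With BTZ, 3 of the 681 genes higher and 2 of the 841 lower in growth medium were past 2-fold the other way in differentiation medium. With TNF-α these were 1 of 134 and 0 of 139.

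Among the 8413 probe sets above the floor with no gene named, 44 were at least 2-fold higher with TNF-α in both media, against 13.1 if the media were independent. With BTZ 87 were at least 2-fold lower in both, against 14.3, and more, 420, were higher in both, against 153. What these probe sets measure was not analysed here. Probe sets that vary more than others would also pass 2-fold in both media more often than independent lists, and this was not tested.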

How the results depend on the processing

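The alternatives were chosen before the data were examined, except the fit without both BTZ arrays and those for genes shared by both media, for genes lower with both treatments and, in part, for the differences between media, which were chosen after seeing the data. No paired analysis was possible because each group holds only replicate 1. A pseudocount of the log2 step was not run, since the values were already log2. Where no construction is named the cause was not tested. Counts of genes stayed within 1.5 times under quantile normalization, shifted arrays and the highest probe set per gene; of the genes past 2-fold with values as deposited, quantile normalization shared 1185 of 1195, 249 of 273, 1385 of 1522, 375 of 394 and 1897 of 2042 in the order medium, TNF-α and BTZ in growth medium, TNF-α and BTZ in differentiation medium. By construction the 1.5-fold threshold gave more genes and 3-fold fewer: higher and lower were 1555 and 1350, then 258 and 239 for the medium; 717 and 639, then 41 and 31 for TNF-α in growth medium; 2005 and 1871, then 127 and 318 for BTZ in growth medium; 740 and 563, then 102 and 29 for TNF-α in differentiation medium; 2161 and 2404, then 212 and 490 for BTZ there. Differences between media gave 946 positive and 806 negative, then 64 and 19, for TNF-α, and 1466 and 1917, then 103 and 208, for BTZ. Genes shared by both media were 226 higher and 183 lower, then 27 and 11, for TNF-α, and 1180 and 1130, then 64 and 155, for BTZ. The floor at the 75th percentile, which tests fewer genes, left 77 lower with TNF-α in differentiation medium and 157 positive and 71 negative for TNF-α between media; with no floor the negative ones were 256.

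In the additive fit 39 counts stayed within 1.5 times and 37 did not. Leaving out 1 array, which leaves 1 residual degree of freedom and assumes a lone array to vary like the others, gave 1 to 1685 genes higher and 0 to 1578 lower for the medium, 0 to 138 and 0 to 86 for TNF-α, and 0 to 1881 and 0 to 1983 for BTZ; at an unadjusted p under 0.05 limma gave 1470 to 4857, 368 to 2037 and 2209 to 5354. For the medium the fit gave 5 and 1 without a covariate and 1657 and 1552 without both BTZ arrays. For TNF-α the genes higher were 5 after quantile normalization and 17 with the stricter floor. Of the 10 ways to split the 6 arrays into 3 and 3, only the real one, 1 of 10, gave as many genes for the medium, 550 against at most 0 for the others (64 to 815 in limma at an unadjusted p under 0.05); in 6 of the other 9 splits the effect rests on 1 pair of arrays, against 3 pairs in the real one, and 10 splits are too few for a share under 0.05.

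List medians kept their sign, except for 30 values of 21 medians inside the random range and for the mean of the unfolded protein and integrated stress list with TNF-α in growth medium, 0.033. For primary lists 118 values moved by less than the spread of random lists and these did not. Sarcomere genes had 3.82 (stricter floor), 3.41 (all members) and 3.27 (mean) for the medium; -0.39 (shifted) and -0.18 (mean) for TNF-α in growth medium; -0.37 (quantile), -0.39 (shifted) and -0.38 (mean) for it in differentiation medium; and -1.98 (quantile), -1.76 (shifted), -2.43 (stricter floor), -1.70 (all members) and -2.03 (mean) for BTZ there. Myogenic genes had 1.25 (stricter floor) for the medium. With TNF-α in growth medium NF-kB targets had 0.80 (shifted), 1.07 (stricter floor) and 1.25 (mean), and in differentiation medium 1.31, 1.501, 1.73 and, with all members, 1.32. Chemokines had 0.60, 0.89, 1.01 and 0.29, then 1.76, 2.48, 2.05 and 1.27, in that order. MHC class I genes had 0.74 (stricter floor) in growth medium. Wasting genes had -0.12 (shifted) and 0.028 (mean), and -0.0089 (shifted) in differentiation medium. With BTZ the means were 0.70 and 0.97 for the proteasome, 0.49 and 0.94 for the unfolded protein list, and 1.16 for NRF2 genes in differentiation medium. Of the named genes, 11 moved with the highest probe set, among them Slc7a11 with BTZ, to 3.64 and 5.04, and Car3 with TNF-α in growth medium, to -5.52. Arrays give no depth; near the floor, background compresses folds.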

Other observations

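The tests and gene groups in this part were chosen only after the results were seen.

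Families outside the fixed lists were looked at too, without comparison to random lists. Of 16 replication-dependent histone genes above the floor, 12 were at least 2-fold lower in differentiation medium (median -1.61) and 13 with BTZ in growth medium (median -1.62), with H1f5 at -3.83 and -3.61. With BTZ in differentiation medium 5 were lower (median -0.52), and with TNF-α the medians were 0.43 and 0.20. Of 13 small nucleolar RNA host genes, 6 were at least 2-fold higher with BTZ in differentiation medium (median 0.94) and 3 in growth medium (median 0.60), with Snhg12 at 3.01 and 3.10 and Snhg15 at 2.89 and 2.01, while Snhg18 stood at -0.71 and -0.38. TNF-α gave this group a median of 0.76 in growth medium and 0.15 in differentiation medium. Of 13 small leucine-rich proteoglycans, which bind collagen fibrils, 6 were lower with TNF-α in each medium (medians -0.84 and -0.71) and 8 with BTZ in each (medians -1.24 and -1.58), while 1, Nyx, was higher with BTZ by 1.39 and 1.22. None of these medians changed sign after quantile normalization or with shifted arrays.

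Genes higher with TNF-α were followed under BTZ. Of the 274 genes at least 2-fold higher with TNF-α in differentiation medium, 74 were at least 2-fold lower with BTZ in growth medium, a pair of comparisons with no shared array, against 16.9 if independent, and 19 were higher, against 13.7. Without the mitotic and replication lists this was 57 of 257, and the number expected for that set was not computed. Cell cycle genes outside those lists stay in it, such as the replication-dependent histone gene H1f5 at 1.01 and -3.61. Of the 134 genes higher with TNF-α in growth medium, 24 were lower with BTZ in differentiation medium, against 11.9, and 26 higher, against 8.11.

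At least 2-fold higher in all 4 treated cultures were 9 genes: Abcb1b, Casp4, Ier3, Lilrb4a, Mmp13, Nabp1, Rhbdf2, Rnd1 and Vegfc. Uchl3, a ubiquitin hydrolase, differed by 1.13 with TNF-α in growth medium and -1.07 in differentiation medium.

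Muscle genes were lower with BTZ in differentiation medium. Whether BTZ had only removed myotubes was asked of 24 sarcomere and excitation-contraction transcripts at least 3 log2 units higher in differentiation medium. Their untreated level there was 8 to 12, and transcripts less than 0.5 above the floor with BTZ were left out. If all myotubes held the same mix of transcripts, such a loss would leave these at about the same share. With the untreated growth medium level subtracted, the 75th percentile of that share was 5.01 times the 25th (23.9% against 4.78%). This argues only against an even loss of myotubes of like content as the whole cause. Loss of myotubes that differ in content from those left would also give unequal shares, and was not tested. Low shares rest on levels near that base, such as Tnni2 at 5.76 against 5.88. Without subtraction the log2 differences ran from -5.27 for Chrng to 0.27 for Xirp1. Xirp1 was also higher with BTZ in growth medium (6.28 against 5.25). Well above the base, Ttn stood at -0.79 and Myh3 at -3.77. Array scaling common to genes of the same level is argued against, since the sarcomere median lay 1.64 below the lower end of the random range. RNA quality was not settled by this. A loss that differs between transcripts of the same level would not show in the random lists. A culture that had differentiated less cannot be told apart, since mitotic genes, with a median of -1.10, were also lower with BTZ in growth medium and each group is 1 culture. A direct effect of BTZ on muscle transcripts was not tested.

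Interferon-stimulated genes showed a larger TNF-α effect in differentiation medium. A lower starting level there is argued against, since the treated arrays themselves differed by a median of 0.95. Array scaling is argued against by a difference 0.52 above the upper end of the random range. Background stays open, since the random lists were not chosen for genes that TNF-α raises. The interferon list also lay near the floor in growth medium, with median levels of 5.33 untreated and 5.81 with TNF-α. Its difference was taken only over the 25 members above the floor, of 37 measured. A weaker stimulus in the growth medium culture stays open, because NF-kB targets had a larger effect in differentiation medium too, by a median of 0.36, and the different state of the cells in the 2 media is an open biological explanation that was not tested.

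At least 2-fold lower in all 4 treated cultures were 31 genes, among them Car3, Omd, Aspn, Ogn, Prelp, Igf1, Cxcr4 and Dhrs3. Shared control arrays are argued against as the whole cause, since the pairs with no shared array overlapped at least 6.76 times more than independent lists. A general fall of matrix genes stays possible, since the matrix list was lower in all 4 comparisons. Its highest median was -0.29 (-0.175 over all measured members). Of the 31 genes 3 are in that list, which holds 35 of the 13652 genes above the floor. The list leaves out the small leucine-rich proteoglycans Omd, Aspn, Ogn and Prelp. Culture density was not tested.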
